A study of Drosophila melanogaster with 3 samples.

How the data were processed

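Anti-GFP chromatin immunoprecipitation was measured in 3 biological replicates of whole embryos aged 0 to 24 h expressing Labial fused to GFP. Per the labels, chromatin was sonicated to 200 to 800 bp. Per the deposited file descriptions, each replicate's narrowPeak list holds peaks together with background as input for IDR, called on that replicate's alignments against a control that the 3 replicates share. A pooled list was called on all 3 together, and the optimal IDR list was derived from these. The deposited signal of each peak and its −log10 q-value are the authors' values; the q-value reached its highest value of 4.15 for 7046 IDR peaks, so peaks were ranked by signal. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Read depth is unknown, and intervals cover counting error only.

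The IDR list was compared with the pooled list and was exactly its 10160 peaks of highest signal (33.9%), so it is a threshold on rank. No interval with its signal was shared between replicate lists, so the replicates were counted as separate. Peak ends of the dm6 lists lay within the arms of the reference, NCBI Release 6, the dm6 coordinate system. On these arms the ends of the dm3 lists did too, so this does not tell the builds apart. The build was taken as the deposited lists name it. Genes came from Ensembl release 115, with 13968 protein-coding genes. The dm3 lists were counted and not placed on a genome. Coordinates are 1-based.

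Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Peaks matched at a reciprocal overlap of at least 50%, against the same number of strongest peaks of each replicate and 100 random placements. Summits were classed, in this order, as promoter (within 500 bp of a protein-coding start site), 5' UTR, coding exon, 3' UTR, intron or intergenic, and compared with 1000 placements within the same arm in a two-sided permutation test. The 20 gene lists were tested for promoter peaks with two-sided Fisher's exact tests and for summits over the gene with 1000 bp flanks against 100000 random lists matched on gene length in 10 bins. The 14 motifs were tested on both strands within 100 bp of the summit against the window 500 bp downstream in an exact McNemar test, and control shares are means of both sides. Trends over 10 rank bins used 100000 resamples. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Pooled-list peaks were counted as outside the IDR list when they matched no IDR peak, which left 18920 of 19840. No paired analysis was possible because there is 1 group. Means and SD are over the 3 replicates' own lists.

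Lists, motifs, tests and the rule for named genes were fixed before the data were examined. The trend test of the promoter share over rank bins was not among these tests, and its p-value is unadjusted. The rule named the gene nearest each of the 10 strongest peaks matched in all 3 replicates, every homeotic gene and Hox cofactor, and at most 3 members of each other list by strongest promoter peak. The older symbols h, svb and Tdrd were read as hry, ovo and Tdrd3; nos matched 2 genes and was left out. Alternatives changed the overlap rule, the start site window, the flanks, the motif window and control, the number of peaks and each replicate in turn. For promoter peaks of gene lists, leaving out a replicate replaced the IDR list by genes bound in both remaining replicates' own lists. Placement by local shifts of 10 to 50 kb or matched on GC content, reordered motifs and genes bound in most replicates were added after the data were seen. The comparison with up to 1000 reordered versions was added after that with 100 and after no motif had passed that one once adjusted over 7 motifs; more versions allow smaller p-values. Reordered versions with fewer than 20 control matches were left out.

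The overlap rule was checked against bedtools 2.31.1, with 0 differences over 9 comparisons of the 10160 peaks. On simulated data over the same 10160 summits, 0 of 40 random sets were called in the placement test, and a planted promoter excess of 2.54-fold was measured as 2.56-fold. Of 200 random lists of 12 genes among the 13968, Fisher's exact test called 15 and the length-matched test 8. Lists of 12 genes with 75% bound were called in 95 of 100 simulations, and those with 50% bound in 44 of 100. Fisher's exact test and the length-matched test gave the same counts here, so these simulations cannot show how the tests differ where binding depends on gene length. The gene list calls, random lists included, used an unadjusted threshold, so how often such lists pass after adjustment was not measured. The motif test called 3 of 70 tests on randomly placed summits, at an unadjusted threshold; 150 planted sites gave an exact p of 3.3e-09 and 50 an exact p of 0.18.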

Results

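Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos aged 0 to 24 h, of both sexes, from a transgenic line that carries Labial fused at its C terminus to GFP. Labial (lab, FBgn0002522) is the most anterior homeotic transcription factor of the Antennapedia complex and acts in the embryonic head and midgut. There was 1 group with 3 biological replicates, precipitated with an antibody against GFP. Each replicate had a list of 30000 ranked peaks, the pooled reads had another list of 30000, and an irreproducible discovery rate (IDR) threshold left 10160 peaks in the dm6 build. The number of reads per replicate was not used here and is unknown, so no value carries an error from depth. Peak signals are the authors' own values and serve only to rank peaks within a list; no sample without the fusion was analysed here.

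The strongest peak found in all 3 replicates lay at the promoter of Ugalt (FBgn0024994), a UDP-galactose transporter gene, at X:2703656-2704116 (dm6), with its summit 26 bp from the transcription start site and a signal of 11184.6. It ranked 1, 2 and 1 in replicates 1, 2 and 3. The peak of rank 2 lay in an intron of ush at 2L:480562-481358, 1369 bp from the nearest start site, that of cbt, and the peak of rank 3 in an intron of CG11050 at 2L:6612413-6612955. CG14100, PNPase, mRpL41 and px followed with promoter peaks of signal 7958.4, 6483.9, 6371.8 and 6066.6. Trl, which encodes the GAGA factor, and Lk6 had intronic peaks of signal 6499.7 and 6196.3, and the peak nearest CG4004 was intergenic, 5016 bp from its start site.

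How far the replicates shared peaks was measured first. Of the 10160 IDR peaks, 73.3%, 77.6% and 77.95% had a partner with at least 50% reciprocal overlap among the 10160 strongest peaks of replicates 1, 2 and 3, a mean of 76.3% ± 2.59 (SD, n = 3), against 2.15% for randomly placed peaks. All 3 replicates matched 5669 IDR peaks (55.8%), and no replicate matched 693 (6.82%); at a reciprocal overlap of at least 80% all 3 replicates matched 33.1%. The strongest 10160 peaks of any pair of replicates shared 72.4% ± 1.54 (SD over 3 pairs). The replicates' ranks had a mean Spearman rho of 0.813 across IDR peaks, which are not independent replicates. This rho covers only IDR peaks with a summit within 100 bp in both replicates' whole lists, 9281 to 9417 per pair. In the strongest of 10 equal rank bins 92.7% of IDR peaks were matched in all 3 replicates, and in the weakest bin 5.02%. Only each replicate's 10160 strongest peaks could match, so weak IDR peaks that ranked below this limit in a replicate went unmatched by construction. Against the replicates' whole lists, all 3 matched 80.5% of IDR peaks. The share matched in all 3 replicates was 52.7% in rank bin 3, where the median peak was 218 bp wide against 424 bp in weaker bins, while 98.1% of the summits in that bin had a replicate summit within 100 bp. The IDR list was made from the same replicates and each list was called against the same control, so these shares are not independent evidence of binding.

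Promoters held more IDR summits than random placement within the chromosome arms, and coding exons held few. Of the IDR summits, 3581 (35.2%) lay within 500 bp of a protein-coding start site, and the replicates' own lists gave 36.4% ± 1.76 (SD, n = 3). Random placement gave 11.5%, a 3.07-fold difference. Coding exons outside promoters held 34 summits (0.335%) against 13.9% under random placement, and 3' UTRs held 1.34% against 4.49%. The coding exon fold was 0.0241, and 0.0394 against placement matched on GC content. Introns held 44.0% against 39.2%, and intergenic sequence 18.3% against 30.1%. Each of these 5 classes had an adjusted p of 0.0024 in a permutation test with 1000 placements, from the smallest p that these can give. Over the alternatives the promoter fold ranged from 2.20 with a 1000 bp start site window to 4.40 with a 250 bp window. It was 2.47 against local shifts of 10 to 50 kb. The intergenic fold ranged from 0.526 for the 5080 strongest peaks to 0.855 against local shifts, which put 21.5% there. The intron fold ranged from 1.03 with a 1000 bp window to 1.18 with a 250 bp window, and was 1.04 against GC-matched placement. All of these values stayed past the threshold. The 5' UTR share of 0.748% did not differ detectably from 0.788% (permutation test, adjusted p = 0.70). It was lower with a 1000 bp start site window (0.577-fold, permutation test, adjusted p = 0.0048), against local shifts of 10 to 50 kb (0.759-fold, adjusted p = 0.014) and for the 5080 strongest peaks (0.677-fold, adjusted p = 0.042). It had 1.07-fold both with a 250 bp window and against placement matched on GC content, and over all alternatives the adjusted p ranged from 0.0048 to 0.63. The promoter share went from 54.3% in the strongest rank bin to 26.0% in the weakest (unadjusted permutation p = 2e-05, the smallest possible), in a test that was not planned. Among the 18920 pooled-list peaks that matched no IDR peak at 50% reciprocal overlap, 15.5% lay in promoters, an odds ratio of 2.96 for IDR peaks (Fisher's exact test p = 2.1e-311). That test counts peaks of 1 pooled list, which are not independent replicates. Among all 19840 pooled-list peaks below the IDR peaks the share was 16.3%.

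**Figure D1:**
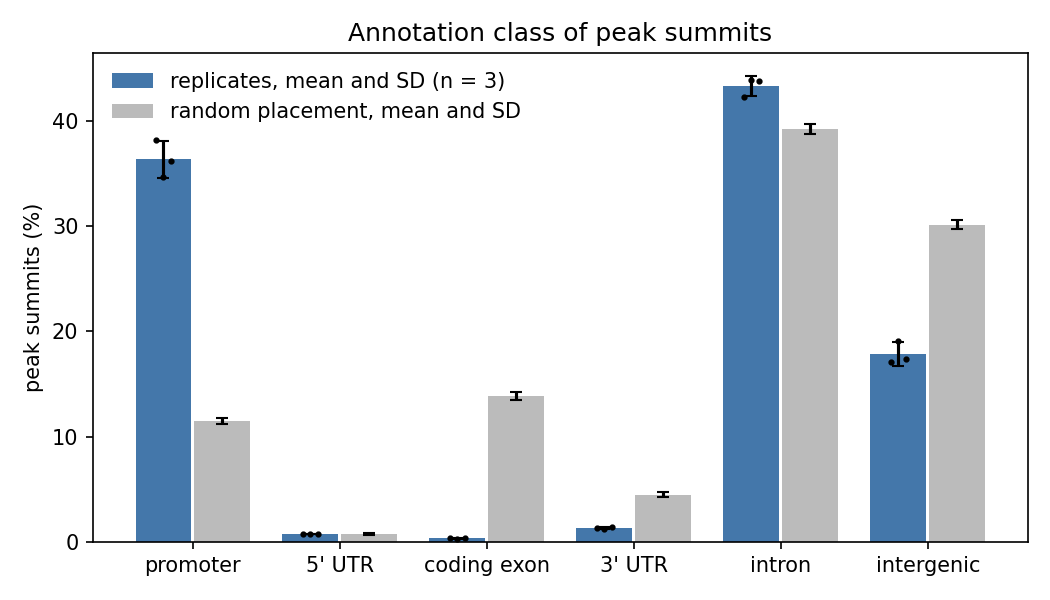
Percentage of peak summits (y axis) in each of 6 annotation classes (x axis). Blue bars and points show the replicates' 10160 strongest peaks, as mean and SD of 3 replicates, and grey bars the mean and SD of 1000 random placements. Promoters reach 36.4% in the replicates against 11.5%, and coding exons 0.358% against 13.9%.

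Summit density ran from 71.7 to 82.4 per Mb on the large arms and was far lower on chromosome 4. The IDR list held 82.4 summits per Mb on 2L, 71.7 on 2R, 78.7 on 3L, 74.9 on 3R and 75.8 on X. The replicates gave 82.2 ± 0.455 on 2L and 73.4 ± 1.07 on 2R (SD, n = 3), and differences between the large arms were not tested. Chromosome 4 held 9 summits, 6.68 per Mb, and the replicates gave 7.91 ± 3.34 per Mb (SD, n = 3). Of its 80 protein-coding genes, 3 had a promoter peak (3.75%, exact 95% interval 0.78% to 10.6%), against 25.6% on the other arms. These were RpS3A, zfh2 and PlexA, named after their values were seen.

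A promoter peak was present at 3558 of 13968 protein-coding genes (25.5%), and the replicates' own lists gave 3691 ± 243 genes (SD, n = 3). Cytosolic ribosomal protein genes had one at 74 of 86 members (86.0%), in Fisher's exact test against all other genes (adjusted p = 6.4e-31), with 73, 71 and 71 members in the 3 replicates. RpL7, RpS27 and RpL23A led them with signals of 4321.8, 3667.7 and 3207.0. No sample without the fusion was analysed here, so these peaks cannot be told apart from signal that does not depend on Labial. Chemosensory receptor genes had a promoter peak at 2 of 179 members, Gr21a and Gr63a (1.12%, Fisher's exact test, adjusted p = 3.2e-19), with 2 members in each replicate. Cuticle protein genes had 1 of 108, Cpr65Av (0.926%, Fisher's exact test, adjusted p = 6.2e-12), and odorant binding protein genes 2 of 51, Obp99b and Obp83g (3.92%, adjusted p = 3.7e-04). Endoderm and midgut regulators had 9 of 12 (75%, Fisher's exact test, adjusted p = 0.0018), with 8 in each replicate. Among them were fkh, a gut forkhead factor, at signal 3488.3, tin, better known as a factor of the heart and visceral muscle, at 1401.1, and GATAe, a gut GATA factor, at 452.5. In the permutation test against random lists matched on gene length the endoderm list (adjusted p = 0.098) and the odorant binding list (adjusted p = 0.14) did not pass. Matched lists had promoter peaks at 38.8% and 14.0% of genes, which gave 1.93-fold for the endoderm list and 0.279-fold for the odorant binding list. With the 5080 strongest IDR peaks the endoderm list had an adjusted p of 0.34 in Fisher's exact test, and over all alternatives it ranged from 4.3e-04 to that value; the odorant binding list ranged from 3.9e-05 to 0.14. The odds ratio of the endoderm list was 8.80 in the IDR list and 2.48 for the 5080 strongest peaks. It was 5.01 without replicate 1, 4.57 without replicate 2 and 7.12 without replicate 3. These values count genes bound in both remaining replicates' own lists, so they differ from 8.80 by more than the replicate left out. Genes bound in most of the replicates' own lists gave 5.66. Over the alternatives tested with Fisher's exact test, odds ratios ranged from 0 to 0.0665 for chemosensory receptors, from 0 to 0.0897 for cuticle proteins and from 0.0759 to 0.202 for odorant binding proteins. Counted in the same way, chemosensory receptors had 0.018 without replicate 2 and 0.0196 without replicate 3, against 0.0325 in the IDR list. Cuticle proteins had 0 without replicate 3, against 0.0271 in the IDR list. Fisher's exact test treats genes as separate units, but neighbouring genes can share a summit and were not grouped. Its p-values therefore do not measure a spread between replicates.

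The other 15 lists did not pass Fisher's exact test after adjustment. Heat shock genes had 5 of 10 members with a promoter peak, led by Hsp83, Hsp27 and Hsp26 with signals of 4792.9, 3173.5 and 1058.0 (exact test, adjusted p = 0.34). Epidermis and trachea markers had 6 of 12, led by trh, crb and shg (exact test, adjusted p = 0.25). Proteasome subunits had 11 of 32, led by Rpn3, Rpn5 and Prosbeta2 (exact test, adjusted p = 0.68). Male-specific transcripts had 1 of 22, Mst85C (exact test, adjusted p = 0.082); with a 250 bp start site window they had an adjusted p of 0.027, within a range of 0.027 to 0.52 over the alternatives. Pair-rule genes had 1 of 9, hry, segment polarity genes 4 of 12, led by nkd, ptc and wg, and glia markers 3 of 8, moody, pnt and loco. Neural progenitor and head regulators had 4 of 23, led by scrt, pros and nerfin-1, and these 4 lists each had an exact adjusted p of 0.79. Gap and terminal genes, led by cnc, cad and hb, and muscle markers, led by sls, Mef2 and Act87E, each had 4 of 14. Neuron markers had 3 of 10, elav, Syx1A and Syt1, germ cell markers 3 of 9, bgcn, Tdrd3 and vas, and hemocyte and fat body markers 2 of 11, ush and srp. Each of these 5 lists had an exact adjusted p of 0.85. The homeotic genes (lab and Antp) had 2 of 8 and the Hox cofactors (hth) 1 of 6, each with an exact adjusted p of 1.

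Summits were also counted over each gene with 1000 bp on either side. Ribosomal protein genes held 110 summits, 3.74 times the number in random lists matched on gene length (permutation test, adjusted p = 1.3e-04). Chemosensory receptor genes held 12 summits (0.147-fold) and cuticle protein genes 8 (0.186-fold), both with the same adjusted p, which comes from the smallest p that the resamples can give. With 5 kb flanks the folds were 2.17, 0.419 and 0.387 for these 3 lists, and over all alternatives they ranged from 1.51 to 4.86, from 0.0793 to 0.419 and from 0.0838 to 0.387. Neural progenitor and head regulators held 14 summits, 0.307 times the matched number (permutation test, adjusted p = 0.014). Without matching on length the ribosomal list had a 1.51-fold difference (permutation test, adjusted p = 0.13, the highest over the alternatives from 1.3e-04). The neural list had 0.723-fold without matching (permutation test, adjusted p = 0.74) and 0.549-fold when genes with at least 1 summit were counted (adjusted p = 0.054), within a range from 4.0e-04 at 0.089-fold for the 5080 strongest peaks. The other 16 lists did not pass. Among them odorant binding proteins had 0.334-fold (permutation test, adjusted p = 0.053), with a range over alternatives from 1.3e-04 without matching on length to 0.41. Endoderm and midgut regulators, also among these lists, held 30 summits, 1.25 times the matched number (permutation test, adjusted p = 0.63). Their fold over the alternatives ranged from 0.929 for the 5080 strongest peaks to 2.96 without matching on length, and none passed.

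Among the homeotic genes, lab itself had 8 IDR summits within 5000 bp of the gene (3R:6661427-6678590), of which 3 were matched in all 3 replicates. Its strongest peak, at 3R:6678519-6678650, lay at the promoter, 27 bp from the start site, with a signal of 788.3 and rank 1537. It was 1 of the narrow peaks: 1 replicate matched it by overlap, but summits within 100 bp had ranks 1862, 1694 and 1366 in the replicates. Any copies of this region that the transgene may carry were not separated from the gene itself in these lists. Antp, a longer gene, had 8 summits, 4 of them matched in all replicates, the strongest at 3R:6912420-6912630 in an intron. Ubx had 2 summits, abd-A and Abd-B 1 each, and Dfd, Scr and pb none. Of the Hox cofactors, hth, whose product carries Exd into the nucleus, had 22 summits with 14 in all replicates and its strongest peak in an intron at 3R:10597618-10597894. disco-r had 2 summits, tsh 1, and exd, disco and tio none. These counts are not scaled by gene length, and Antp (3R:6896253-6999228) and hth (3R:10507561-10639568) are far longer than lab. With 1000 bp flanks, homeotic genes held 0.662 times and Hox cofactors 1.87 times the summits of random lists matched on gene length. Neither differed detectably (permutation test, adjusted p = 0.61 and 0.36).

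The sequences at the summits were compared with windows 500 bp away. The site for Labial with its cofactor Exd, TGATKGAT, was within 100 bp of 339 IDR summits (3.34%) against 2.06% of control windows, a 1.62-fold difference (exact McNemar test, adjusted p = 1.4e-07). The replicates' own lists gave 1.66-fold ± 0.0926 (SD, n = 3). The core promoter elements DRE, found at many housekeeping genes (1.98% against 0.561%, exact adjusted p = 1.1e-21), and Motif 1 (1.11% against 0.29%, exact adjusted p = 5.4e-09) differed by 3.53-fold and 3.83-fold. The replicates' own lists gave 3.73-fold ± 0.362 for DRE, 4.29-fold ± 0.307 for Motif 1 and 1.46-fold ± 0.0444 for GATA sites (SD, n = 3). GATA sites (1.48-fold, exact adjusted p = 1.4e-05), Exd-Dfd/Scr type sites (1.39-fold, adjusted p = 0.017) and the homeodomain core TAATTA (1.14-fold, adjusted p = 0.0089) were more frequent at summits, and CAGGTG less (0.806-fold, adjusted p = 8.5e-05). Under alternatives in windows, controls and peaks, the GATA call alone passed in every exact test. The Exd-Lab call was lost against the unmatched pooled-list peaks (1.10-fold, exact adjusted p = 0.28, with a range over these alternatives from 2.0e-09), and the DRE and Motif 1 calls were lost outside promoters. Exd-Dfd/Scr sites did not pass within 200 bp (1.11-fold), in IDR peaks matched in all 3 replicates (1.27-fold), against the unmatched pooled-list peaks (1.12-fold) or outside promoters (1.47-fold), with exact adjusted p from 0.0031 to 0.78 over these alternatives. TAATTA did not pass within 200 bp (1.05-fold) or outside promoters (1.07-fold), with exact adjusted p from 6.7e-10 to 0.55, and CAGGTG did not pass against the unmatched peaks (0.957-fold) or outside promoters (0.894-fold), with exact adjusted p from 5.5e-07 to 0.50. The other 7 motifs did not pass, among them a single reordered Exd-Lab site (1.14-fold, exact adjusted p = 0.63).

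Each called motif was also set against up to 1000 reordered versions of itself, a comparison chosen after the data were seen. DRE (permutation test, adjusted p = 0.024, none of 591 versions as extreme) and Motif 1 (adjusted p = 0.035, 4 of 1000 versions) passed. The Exd-Lab site did not, with 29 of 1000 versions as extreme (permutation p = 0.06, adjusted p = 0.10), nor did GATA (adjusted p = 0.10), CAGGTG (adjusted p = 0.84) or the Exd-Dfd/Scr site (adjusted p = 0.85). Relative to the median reordered version, the folds of these motifs were 1.44, 1.38, 0.952 and 1.03, in this order. TAATTA had 13 reordered versions, so its permutation p could not fall below 0.14 and this comparison could not pass; all 13 had a higher fold than TAATTA itself. A first run with 100 versions gave the Exd-Lab site an unadjusted permutation p of 0.04 and an adjusted p of 0.092, and no motif passed after adjustment. Outside promoters the Exd-Lab and GATA sites alone remained past the threshold among the motifs more frequent at summits, DRE having 1.18-fold and Motif 1 1.83-fold (exact adjusted p = 0.82 each). Inside promoters DRE was at 4.80% of summits against 0.908% of control windows, and the Exd-Lab site at 1.79% against 1.42%. Motif 1 had 2.51-fold against the unmatched pooled-list peaks. The Exd-Lab site was at 3.34% of IDR peaks and 3.03% of the 18920 unmatched pooled-list peaks (Fisher's exact test p = 0.16). Some directions depended on the window or the comparison. GAGA sites had 1.09-fold at summits (exact adjusted p = 0.096). They passed as more frequent within 200 bp (1.40-fold), with controls 1000 bp away (1.31-fold), against the unmatched pooled-list peaks (1.30-fold) and in the replicates' own lists averaged without each replicate in turn (1.16-fold to 1.17-fold). They passed as less frequent within 50 bp (0.774-fold) and outside promoters (0.779-fold), and over all these alternatives the exact adjusted p ranged from 1.1e-16 to 0.65. In narrow windows stepped away from the summit, GAGA sites were at 0.797% of IDR peaks at the summit itself. They were at 2.13% and 1.77% at 100 bp on either side, and at 1.20% and 1.18% at 500 bp. Windows of 50 bp leave out these higher shares and those of 200 bp include them. Inside promoters 7.46% of summits had a GAGA site against 4.43% of control windows, and outside 3.53% against 4.53%. Grainyhead sites had 0.667-fold (exact adjusted p = 0.093) and passed as less frequent within 50 bp (0.439-fold, adjusted p = 0.012, with a range over alternatives from that value to 0.73). Hth sites had 1.06-fold (exact adjusted p = 0.36) and 0.84-fold against the unmatched pooled-list peaks, past the threshold.

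**Figure D2:**
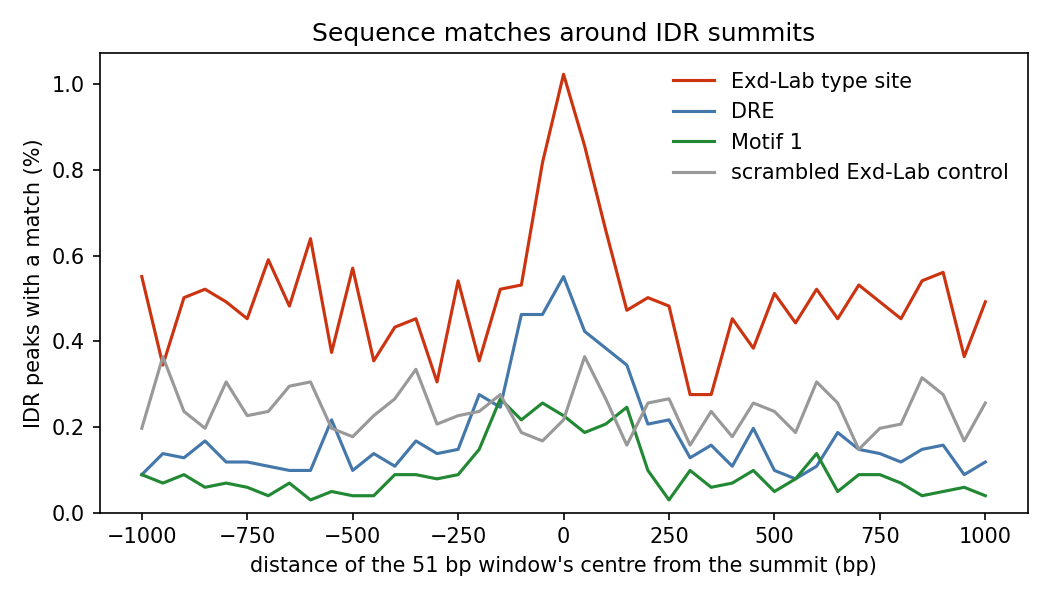
Percentage of IDR peaks with a sequence match (y axis) in windows centred at increasing distance from the summit in bp (x axis). Lines show the Exd-Lab type site, DRE, Motif 1 and a single reordered Exd-Lab site. The Exd-Lab line reaches 1.02% at the summit, against 0.571% and 0.512% at 500 bp on either side. The reordered site has 0.217% at the summit, against 0.177% and 0.236% there.

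Matches were then followed over 10 bins of signal rank. The share of peaks with TAATTA went from 17.03% in the strongest bin to 12.9% in the weakest (permutation test, adjusted p = 5.6e-04), and that with DRE from 2.46% to 1.38% (adjusted p = 0.025), which did not pass with 5 bins (adjusted p = 0.062) or outside promoters (adjusted p = 0.63). The Exd-Lab site was present at 2.36% of peaks in the strongest bin and 2.95% in the weakest (permutation test, adjusted p = 0.21). No trend passed among summits outside promoters.

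The same libraries gave 10149 IDR peaks in the dm3 build, 11 fewer than in dm6. Chromosome 4 held 4 of them, against 9 in dm6, and 2 lay on XHet, outside the 6 arms. Coordinates were not converted between the builds.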

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

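The tests of the strength threshold of the list, of the gene content of chromosome 4 and of its repeat-masked sequence were chosen only after the results were seen. Placement matched on GC content was added after the data were seen, before its own values were known. No biological explanation was tested for the patterns below, since there was 1 group of 3 samples.

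Coding exons held 0.335% of IDR summits against 13.9% under random placement. GC content alone does not account for this, since placements matched on GC content put 25.4 times the observed share there. Nor does the rank cut within the pooled list alone. Of its lower-ranked peaks 1.54% lay in coding exons, more than the 0.335% of IDR summits but far below 13.9%. The pooled list holds only 30000 called peaks, so weaker signal was not covered. The promoter class taking such bases does not account for it either, since 0.837% of summits lay on any coding base against 17.02% expected. An effect of the control reads or of the peak calling could act in the same way and stays open, as the control was not analysed here.

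Chromosome 4 held 9 summits. A low gene number does not explain this, since 3.75% of its genes had a promoter peak against 25.6% elsewhere. Placements matched on GC content put a median of 128 summits there, and unmasked bases alone predicted 91.1. How the alignment treated reads from repeats was not analysed here and stays open.

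The lab gene with 5000 bp flanks held 16 summits of the pooled list, 3.27 times the density of the 50 kb on either side. Extra copies of the region, if the transgene carries them, could raise this density. It lay at percentile 93.6 of genes of similar length, and the exact Poisson interval of the count spans percentiles 67.6 to 99.9, around the bound of 95 set before. The use of this interval was decided after the value was seen. The value therefore lies on the side set for no effect of copies, but by less than its counting error. Extra copies and binding of Labial at its own gene cannot be told apart, because the count is small and no sample without the fusion was analysed here. A count of called summits also does not measure copy number.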

How the results depend on the processing

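Placement by shifts or matched on GC content, the alternatives for peaks matched in all 3 replicates, genes bound in most replicates and both sets of reordered motifs were chosen only after the data were seen. Of 584 alternative values over 81 results, 456 kept their direction and side of the threshold or moved within the replicate spread, 27 lost the threshold, 12 gained it, 30 moved further and 59 changed direction. Of the direction changes, those of TAATTA against reordered versions (0.847-fold over the median of its 13 versions in both sets, which are too few for a p below 0.14) began from a called result. Causes were not tested except where construction shows them. Recovery per replicate was 88.7% with any overlap, 59.6% at 80% reciprocal overlap, 83.8% by summits within 100 bp, 87.5% in whole lists and 72.1% for the 5080 strongest peaks; the share matched in all 3 replicates was 74.2%, 33.1%, 64.7%, 80.5% and 52.2% under these. Leaving out a replicate, which asks for a match in 2 lists in place of 3, gave 62.5% to 64.8%. Pairs of replicates shared 81.98%, 57.8% and 74.3% under the 3 overlap rules, 70.1% for the 5080 strongest, and 71.04% to 74.07% without a replicate. Chromosome 4 held 0.0394% of dm3 peaks. The 5' UTR fold was 1.07 with a 250 bp start site window and 1.07 with GC-matched placement, and was past the threshold at 0.577 with a 1000 bp window, 0.677 for the 5080 strongest peaks and 0.759 against local shifts. Of the lists more often bound at promoters, 1 of 2 passed with the 5080 strongest peaks and 1 with matching on length; over the gene, 0 passed without length matching. For promoter peaks, odds ratios changed direction with a 250 bp window for homeotic genes (1.27) and neuron markers (0.952), and with 1000 bp for gap genes and muscle markers (0.942 each). With length matching the folds were 0.876 for gap genes, 0.802 for segment polarity genes, 0.679 for neuron markers and 0.718 for muscle markers. With the 5080 strongest peaks segment polarity genes had 0.451, muscle markers 0.826 and epidermis markers 0.992, and with peaks matched in all replicates segment polarity and epidermis lists had 0.967 each and hemocyte markers 1.07. With genes bound in both remaining replicates' own lists, homeotic genes had 1.09 to 1.19, and segment polarity genes had 0.651 without replicate 2. For summits over the gene, no length matching gave homeotic genes 2.66, neuron markers 1.06, muscle markers 2.36, epidermis markers 1.78, heat shock genes 0.947, proteasome subunits 0.629 and male-specific transcripts 0.377. Counting genes with at least 1 summit gave Hox cofactors 0.817, gap genes 0.752, segment polarity genes 0.819, hemocyte markers 0.662 and male-specific transcripts 0.407. Flanks of 5 kb gave gap genes 0.969, segment polarity genes 0.968, muscle markers 1.05 and male-specific transcripts 0.739, and among called lists chemosensory receptors 0.419, cuticle proteins 0.387 and ribosomal proteins 2.17. The 5080 strongest peaks gave homeotic genes 1.08, segment polarity genes 0.751 and endoderm regulators 0.929, and peaks matched in all replicates gave segment polarity genes 0.889, endoderm regulators 0.97 and male-specific transcripts 0.762. Motifs more frequent at summits numbered 2 outside promoters, 0 against 100 and 2 against up to 1000 reordered versions, in place of 6; those less frequent numbered 3 within 50 bp (CAGGTG, GAGA and Grainyhead sites, the last at 0.439) and 0 against either set of reordered versions, in place of 1. Exd-Ubx/Abd-A sites had folds of 1.02 within 50 bp, 1.05 with controls 1000 bp away, 1.04 against the unmatched pooled-list peaks and 1.06 in the 5080 strongest. Hth sites had 0.84 against the unmatched peaks and 0.983 outside promoters. GAGA sites had 0.774 within 50 bp and 0.779 outside promoters, both past the threshold, and 0.994 in the 5080 strongest; they were past it as more frequent at 1.40 within 200 bp, 1.31 with controls 1000 bp away, 1.30 against the unmatched peaks and 1.16 to 1.17 without a replicate. Zelda sites had 1.02 against the unmatched peaks, and the reordered Exd-Lab site 0.991 with controls 1000 bp away. CACATGT had 1.03 within 50 bp, 1.02 within 200 bp, 1.04 with controls 1000 bp away and 0.939 to 1.02 without a replicate. Trends over signal rank numbered 1 with 5 bins and 0 outside promoters, in place of 2. Read depth is unknown, so what it limits could not be measured.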

Other observations

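The test below was chosen after the shares it compares were seen. A hypothesis was that Exd-Lab type sites set the position of peaks mainly outside promoters. Outside promoters 4.18% of summits had a site against 2.41% of control windows, and inside promoters 1.79% against 1.42%. Among peaks with a site on a single side, 64.1% had it at the summit outside promoters and 54.8% inside. Fisher's exact test gave p = 0.082, which neither shows a difference nor shows that the shares are equal.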
